A study of Homo sapiens with 24 samples.

How the data were processed

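RNA sequencing counts from 16 libraries were analysed: 4 B-cell lymphoma lines (SU-DHL-10, OCI-LY3, OCI-LY19 and U-2932), each at 0 h and after 8 h of TAK-981, with 2 replicates per group. The values are raw counts per gene as deposited by the authors, with 92 spike-in RNAs in the same table. Per the labels, the protocol included poly(A) enrichment, removal of PCR duplicates and reverse transcription. Per the submitters' processing notes, Trimmomatic, DESeq2, Bowtie2, MACS2, bedtools and HOMER and the builds GRCh38 and hg19 were used, without a role for each. Which aligner, counting program and gene annotation made the counts is not given in the sources used here. The 8 ATAC-seq samples of the series were not analysed here.

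Of 58676 gene IDs, 58207 were matched to a symbol. Total gene counts ran from 16770677 to 24694466 per library. Genes were filtered with filterByExpr on the 8 groups, which left 17327. Counts were normalized by TMM and fitted in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with a quasi-likelihood model. The median biological coefficient of variation was 8.7%. Changes within each line, the difference between lines (3 degrees of freedom) and each line against the mean of the other lines came from a model with 1 mean per group and 8 residual degrees of freedom. The change across lines came from a model with terms for line and time and 11 residual degrees of freedom. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic.

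Before the data were examined, 39 gene lists were fixed, of which 38 had the minimum of 5 tested members. They were tested by camera with a preset correlation between genes of 0.01, and again with an estimated correlation and by fry. The mitochondrial share, the percent of gene counts from mitochondrially encoded mRNAs, was compared by an exact permutation of times within lines. Groups with 0 counts were set against a floor of 3 counts over the group.

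Genes are named by a rule also written before the data were examined: the highest and lowest fold changes across lines and within each line among called genes with a mean of at least 5 CPM, the smallest p-values of the difference between lines, up to 4 members of each list with the smallest p-values, and a fixed set that includes the SUMO genes, MYC, BCL2, BCL6 and IRF4. Genes with symbols of clones, antisense transcripts or pseudogenes were not named.

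The alternatives tried were DESeq2 1.42.0, RLE scaling, total counts without TMM, no filter, a stricter filter, a replicate block, the libraries of 1 line alone, leaving out each library or line, a fold change threshold, the mean of the 4 line contrasts, and scaling by spike-in totals. The pipeline was tested on simulated data with 200 changed genes. For changed genes at 5 CPM or more it recovered 97.4% of 1.5-fold changes across lines, and 77.8% (SU-DHL-10) to 83.8% (OCI-LY19) within a line. Of the simulated calls, 3.7% across lines and 5.3% (SU-DHL-10) to 7.7% (OCI-LY3) within a line were false. It found 3 of 3 shifted lists and called 0 unshifted ones. The simulated genes varied independently of each other, so false list calls among correlated genes were not tested. Far fewer genes changed than were called in the data, with equal numbers up and down, so the scaling was not tested either.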

Results

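Gene expression was measured by RNA sequencing in 4 human B-cell lymphoma lines before and after treatment with TAK-981, a small molecule that inhibits the SUMO-activating enzyme and so blocks the attachment of SUMO, a ubiquitin-like protein, to its targets. The lines are labelled SU-DHL-10, OCI-LY3, OCI-LY19 and U-2932, and each is described as a diffuse large B-cell lymphoma line. The series text names SU-DHL4 where the sample labels say SU-DHL-10, so the identity of that line is in doubt, and the labels are followed here. Each was sampled at 0 h and after 8 h of TAK-981 with 2 replicates per time, which gave 16 libraries in 8 groups. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The spread of a gene was estimated over all groups together, though replicates differed more in some groups. A chi-square between replicates per degree of freedom was 13.63 at 0 h and 2.97 at 8 h in OCI-LY19, and 11.54 and 2.74 in SU-DHL-10. No vehicle sample at 8 h was analysed here, so 0 h was the only reference and the effect of 8 h in culture is part of every value. Total gene counts ran from 16770677 to 24694466 per library. The series concerns mitochondrial function and metabolism in B-cell malignancies under SUMO inhibition, and the comparisons follow the 8 h response in each line, over all lines, and between lines.

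The libraries labelled OCI-LY3 and OCI-LY19 resembled each other at 0 h. Their mean log2 CPM correlated across genes with r = 0.978, against 0.817 to 0.878 for the other 5 pairs of lines, and genes are not independent replicates. A line at 8 h against itself at 0 h had r = 0.967 (U-2932) to 0.994 (SU-DHL-10). IRF4, a transcription factor of activated B cells and plasma cells, stood at 5.76 CPM in OCI-LY3 and 5.45 CPM in OCI-LY19, against 0.04 CPM in SU-DHL-10 and 579 CPM in U-2932. BCL2, which holds back cell death, stood at 64.1 and 101.02 CPM, against 0.29 CPM in SU-DHL-10 and 1141 CPM in U-2932. The number of genes at 10 CPM or more in 1 line and under 0.1 CPM in the other was 1 for this pair and 220 to 334 for the other pairs. Added spike-in RNAs took 0.0494% ± 0.00501 of counts at 0 h in SU-DHL-10 and 0.0769% ± 0.00765 in OCI-LY3, but 0.572% ± 0.0591 in OCI-LY19 and 0.617% ± 0.00438 in U-2932 (SD, n = 2 each). The labels give no batch, and results are given below for the low-share and the high-share lines apart.

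Across the 4 lines, 3128 of 17327 tested genes changed at 8 h, 1737 of them higher and 1391 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8 against 8 libraries with line as a term). Libraries, not lines, were the replicates of this test. Its p-values and standard errors therefore do not measure how the change would vary over other lines. SLC38A2, a neutral amino acid transporter, rose by a log2 fold change of 1.31 ± 0.13 (SE, as for all fold changes that follow), CPEB2, a translational regulator that binds mRNA tails, by 1.25 ± 0.10, and APOLD1 by 1.24 ± 0.12. DHRS2, a short-chain dehydrogenase, rose by 2.49 ± 0.27, and REL, the c-Rel subunit of NF-kB, by 1.29 ± 0.26. Among the genes that fell were MPEG1, a pore-forming protein of phagocytes and B cells (-2.67 ± 0.41), TSC22D3, a glucocorticoid-induced leucine zipper protein (-2.01 ± 0.17), the fructose transporter SLC2A5 (-1.87 ± 0.19) and NLRP7 (-1.58 ± 0.15). IGHG1, the IgG1 heavy chain, also fell (-1.61 ± 0.21), though it shares sequence with other heavy chain genes and the counting is not given in the sources used here. SLC12A7, a potassium-chloride cotransporter, had the highest fold change of the genes named by rule over all lines (5.25 ± 1.20), and its call was lost without either the OCI-LY3 or the OCI-LY19 line (3.35 and 3.42), as it was without replicate 2 of OCI-LY19 at 0 h (4.69). Its mean rose from 4.08 ± 0.504 to 500.5 ± 10.7 CPM in OCI-LY19 and from 0.0877 ± 0.0347 to 225 ± 10.3 CPM in OCI-LY3 (SD, n = 2). The same test called 1911 genes in the low-share lines alone and 1758 in the high-share lines alone. With a replicate block it called 1215. Without SU-DHL-10, OCI-LY3, OCI-LY19 or U-2932 it called 3393, 1409, 2893 and 3385, and the mean of the 4 line contrasts, fitted with a separate change for every line, called 7112.

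Some genes of the SUMO machinery rose. Of 27 tested members, 9 rose, 0 fell and 18 were not called over all genes tested, and 10 rose and 0 fell adjusted over the list alone, with a median log2 fold change of 0.19. By line the median was 0.06 in SU-DHL-10, 0.16 in OCI-LY3, 0.28 in OCI-LY19 (0.04 without TMM scaling) and 0.20 in U-2932. Examples were the SUMO ligase PIAS1 (0.59 ± 0.08), the SUMO protease USPL1 (0.62 ± 0.09) and SUMO3 (0.41 ± 0.07). The subunits of the enzyme that TAK-981 targets, SAE1 and UBA2, stood at 0.03 ± 0.07 and 0.09 ± 0.06 and did not pass the test. SUMO2 passed at 0.37 ± 0.12, but lost its call when any 1 of the 8 libraries of OCI-LY3 and OCI-LY19 was left out (0.29 to 0.38), without either of these lines (0.38 and 0.15), and with a replicate block. With the preset correlation of camera the list was higher than other genes (adjusted p = 4.03e-04), and this did not hold with its own estimate (adjusted p = 0.394 with an estimated correlation).

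Part of the heat shock genes and chaperones rose in the test across lines. Of 18 members, 9 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.49. The cochaperone DNAJB1 rose by 1.02 ± 0.10, the HSP110 chaperone HSPH1 by 0.98 ± 0.14 and the HSP90 cochaperone CHORDC1 by 0.69 ± 0.08. By line the list median was 0.32 in SU-DHL-10, 0.96 in OCI-LY19 and 0.55 in U-2932, and 0.01 in OCI-LY3, where the list was not called and its median was -0.03 without TMM scaling. The list was called by camera with the preset correlation (adjusted p = 2.40e-07) and by fry (adjusted p = 7.61e-04), but not by camera with its own estimate (adjusted p = 0.209 with an estimated correlation).

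Part of the genes of B-cell identity and receptor signalling fell. Of 29 members, 14 fell and 1 rose (18 and 3 adjusted over the list alone), with a median of -0.40. CD79B, a signalling chain of the B-cell receptor, fell by 1.25 ± 0.11 on the log2 scale, the pre-B-cell gene VPREB3 by 1.00 ± 0.12 and the transcription factor POU2F2 by 0.64 ± 0.09. In the germinal centre program 5 of 20 members fell and 0 rose (7 and 0 adjusted over the list alone), among them the migration receptor P2RY8 (-1.17 ± 0.23) and the transcription factor MEF2B (-1.69 ± 0.39), with a list median of -0.54. By line that median was -0.81 in OCI-LY3, -1.10 in OCI-LY19, -0.14 in SU-DHL-10 and 0.01 in U-2932 (-0.01 with RLE scaling). Camera called both lists with the preset correlation (adjusted p = 1.92e-07 and 9.91e-04), as did fry (adjusted p = 5.89e-04 and 0.0194), but camera called neither on its own estimate (adjusted p = 0.209 and 0.530 with an estimated correlation). Lists of other cell types gave mixed values. Of 11 tested T and NK cell genes 2 fell and 0 rose (2 and 0 adjusted over the list alone), with a median of -0.50, and the kinase LCK fell by 0.81 ± 0.08. Camera called that list (adjusted p = 0.0122), but not without the U-2932 line (adjusted p = 0.0659) nor on its own estimate (adjusted p = 0.209 with an estimated correlation). The 4 monocyte and macrophage genes past the filter, too few for a list test, had a median of -0.58 with 0 called. The 7 tested genes of epithelium, stroma and endothelium had 0 called and a median of 0.02, which was -0.03 without TMM scaling and 0.40 with spike-in scaling.

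Some type I interferon response genes were lower at 8 h. Of 45 tested members, 10 fell, 2 rose and 33 were not called (11 lower and 2 higher adjusted over the list alone), with a median of -0.35. By line the median was 0.01 in SU-DHL-10, -0.37 in OCI-LY3, -0.12 in OCI-LY19 and -0.89 in U-2932. Among them were the antiviral genes IFIT3 (-1.47 ± 0.22) and OAS1 (-1.11 ± 0.21), and the nuclease ISG20 (-0.72 ± 0.14). IFNB1, the gene of interferon beta, did not pass the low-count filter and was not tested. The list's camera call (adjusted p = 9.91e-04) was lost without the U-2932 line (adjusted p = 0.0732), and likewise on its own estimate (adjusted p = 0.467 with an estimated correlation).

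Mitochondrial genes did not move alike in the 4 lines. Mitochondrially encoded mRNAs took 3.17% ± 0.00849 of gene counts at 0 h and 3.37% ± 0.157 at 8 h in SU-DHL-10, 3.09% ± 0.271 and 3.53% ± 0.308 in OCI-LY3, 5.23% ± 1.40 and 3.44% ± 0.202 in OCI-LY19, and 5.86% ± 0.0113 and 4.89% ± 0.151 in U-2932 (SD, n = 2). The mean difference over lines was -0.531 percentage points, which did not pass an exact permutation test within lines (two-sided p = 0.150 over 1296 arrangements). Without replicate 2 of OCI-LY19 at 0 h it was -0.284 points. For the mitochondrial ribosome, which translates the mitochondrially encoded mRNAs, 18 of 77 members fell and 0 rose across lines (24 and 0 adjusted over the list alone), with a median of -0.20, which was 0.08 with spike-in scaling. By line its median was -0.12 in SU-DHL-10, -0.15 in OCI-LY3 and -0.53 in U-2932 (0.02, 0.10 and 0.20 with spike-in scaling), and 0.11 in OCI-LY19 (-0.13 without TMM scaling). Examples were MRPS34 (-0.48 ± 0.08), MRPL36 (-0.52 ± 0.09) and MRPS31 (-0.33 ± 0.06). The nuclear genes of respiratory complex I had a median of -0.19 (0.09 with spike-in scaling), with 4 of 37 lower and 1 higher (2 and 0 adjusted over the list alone). Camera called both with the preset correlation and neither on its own estimate (adjusted p = 0.681 and 0.833 with an estimated correlation), fry called the mitochondrial ribosome (adjusted p = 0.0447) but not complex I (adjusted p = 0.150), and without U-2932 the complex I call was lost (adjusted p = 0.701).

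All of these fold changes are relative to the bulk of genes in a library. With scaling by spike-in counts, an alternative added after the data were seen, the median of all tested genes moved from 0.00 to 0.28 across the lines, and to 0.11 in SU-DHL-10, 0.20 in OCI-LY3, 0.00 in OCI-LY19 and 0.70 in U-2932. Across the lines 4293 genes were then called, 4009 higher and 284 lower. The share of higher genes among those called then went from 49.9% to 87.1% in SU-DHL-10, from 51.0% to 81.7% in OCI-LY3 and from 51.1% to 92.6% in U-2932, and stood at 50.8% in OCI-LY19 against 55.1%. Without TMM scaling it was 70.3% in SU-DHL-10 and 26.6% in OCI-LY19, where the median of all genes was -0.20. How the spike-ins were dosed is not given in the sources used here. Across lines with spike-in scaling, against the all-gene median of 0.28, the list medians were 0.77 (heat shock), 0.46 (SUMO), -0.12 (B cell), -0.26 (germinal centre) and -0.06 (type I interferon).

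**Figure D1:**
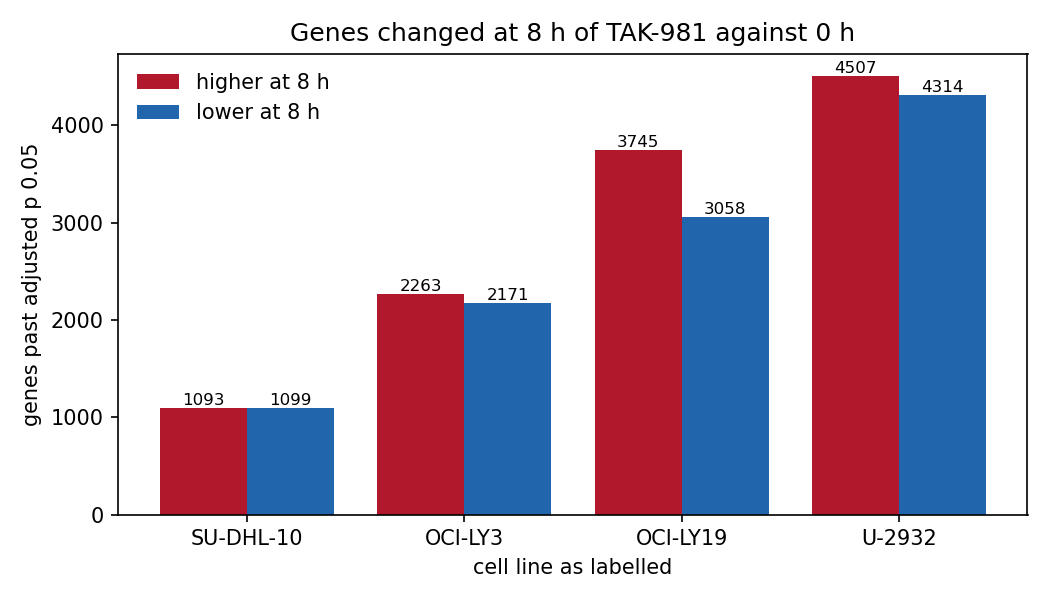
Number of genes past an adjusted p of 0.05 (y axis, genes) in each cell line as labelled (x axis), with bars for genes higher and lower at 8 h of TAK-981 than at 0 h under TMM scaling. Totals run from 1093 higher and 1099 lower in SU-DHL-10 to 4507 higher and 4314 lower in U-2932, and the split into higher and lower depends on the scaling.

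In SU-DHL-10, 1093 genes rose and 1099 fell at 8 h (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 against 2 libraries in a model of all 16). CLIP2, a microtubule linker protein, rose by 3.23 ± 0.12, from 2.76 ± 0.656 to 25.9 ± 1.35 CPM (SD, n = 2), and the adaptor LAT2 by 1.80 ± 0.08. Genes of cholesterol and fatty acid synthesis rose, 14 of 30 with 0 lower (19 and 1 adjusted over the list alone), with a median of 0.25. These included HMGCS1 (1.58 ± 0.09) and MSMO1 (1.05 ± 0.09) of the sterol pathway, the epoxidase SQLE (0.68 ± 0.07) and the desaturase SCD (0.52 ± 0.06). The unfolded protein response list had 9 of 16 members lower and 1 higher (10 and 2 adjusted over the list alone). Its members HSPA5 (-0.92 ± 0.06), HYOU1 (-0.60 ± 0.06) and PDIA4 (-0.50 ± 0.06), all chaperones of the endoplasmic reticulum, fell, while their partner HSP90B1 rose by 1.17 ± 0.07. In the B-cell list 14 of 29 members fell and 3 rose (16 and 5 adjusted over the list alone), and of cytosolic ribosomal protein genes 24 of 75 fell and 0 rose (40 and 0 adjusted over the list alone). The medians of these 2 lists were -0.20 and -0.16, and -0.06 and -0.02 with spike-in scaling, and that of the ribosomal protein genes was -0.04 after a trend with expression level was removed. Camera with the preset correlation called 17 lists, 2 up and 15 down, and called 0 with estimated correlations, where the adjusted p values of the 4 lists above were 0.139, 0.264, 0.336 and 0.336 with an estimated correlation. Without replicate 1 or replicate 2 at 8 h, 1060 and 1084 genes were called, and with spike-in scaling 773.

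In the libraries labelled OCI-LY3, 2263 genes rose and 2171 fell by the same test. GALNT9, a glycosyltransferase gene, had 0 counts at 0 h and 48.3 ± 4.40 CPM at 8 h (SD, n = 2), at least 542-fold higher against a floor of 3 counts over the group, and TRIM29 was at least 171-fold higher on the same floor. BCL6, the master repressor of germinal centre B cells, fell by 2.32 ± 0.08 on the log2 scale, and BLNK, an adaptor of B-cell receptor signalling, by 2.49 ± 0.12. In the B-cell list 22 of 29 members fell and 3 rose (22 and 3 adjusted over the list alone), and in the germinal centre list 14 of 20 fell and 0 rose (14 and 0 adjusted over the list alone). Of the NF-kB target genes 22 of 29 rose and 2 fell (22 and 2 adjusted over the list alone), with a median of 0.80. TNFAIP3, a feedback inhibitor of NF-kB, rose by 1.68 ± 0.06, and TRAF1 by 1.57 ± 0.06. In the ATF4 and amino acid stress list 20 of 31 members rose and 2 fell (23 and 4 adjusted over the list alone), among them PPP1R15A (1.67 ± 0.09), CHAC1 (2.30 ± 0.20) and ATF4 itself (0.59 ± 0.06). Genes of cholesterol and fatty acid synthesis fell, 24 of 30 with 3 higher (24 and 3 adjusted over the list alone), though INSIG1, which holds the pathway back, rose by 1.95 ± 0.09. Camera called 14 lists with the preset correlation and only the NF-kB list with estimated correlations (adjusted p = 0.0360), while the B-cell, germinal centre, ATF4 and cholesterol lists each stood at adjusted p = 0.0679 with an estimated correlation.

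In OCI-LY19, 3745 genes rose and 3058 fell by the same test. NF-kB target genes rose, 27 of 29 with 0 lower (27 and 0 adjusted over the list alone) and a median of 1.79. The adhesion molecule ICAM1 rose by 2.54 ± 0.07, from 193 ± 11.8 to 1123 ± 4.49 CPM (SD, n = 2), TRAF1 by 2.44 ± 0.06 and the precursor subunit NFKB1 by 2.27 ± 0.06. In the unfolded protein response list 13 of 16 members rose and 2 fell (13 and 2 adjusted over the list alone), with HSPA5 at 1.89 ± 0.06 and HERPUD1, a component of degradation at the endoplasmic reticulum, at 1.73 ± 0.08. Proteasome and ubiquitin genes rose in 30 of 36 cases with 1 lower (31 and 1 adjusted over the list alone), such as PSMC3 (0.58 ± 0.06), and 14 of 20 class I antigen presentation genes rose with 2 lower (14 and 2 adjusted over the list alone), such as the chaperone CALR (1.62 ± 0.06). Of the germinal centre genes 14 of 20 fell and 1 rose (16 and 1 adjusted over the list alone), with P2RY8 at -2.43 ± 0.08 and the exception SERPINA9 at 2.38 ± 0.10. For the nuclear genes of complex I, 17 of 37 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.20 that was -0.03 without TMM scaling. Camera called 19 lists with the preset correlation and only the NF-kB list with estimated correlations (adjusted p = 0.00717), and the unfolded protein response, proteasome, class I, germinal centre and complex I lists stood at adjusted p = 0.0920, 0.135, 0.135, 0.135 and 0.260 with an estimated correlation. With spike-in scaling 4206 genes were called. The make-up of these libraries also moved with time. Mitochondrial rRNA took 1.315% and 1.568% of gene counts at 0 h and 0.870% and 0.884% at 8 h. Gene IDs without a symbol took 0.08312% and 0.08065% at 0 h and 0.1398% and 0.1394% at 8 h.

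In U-2932, 4507 genes rose and 4314 fell by the same test. Genes of the plasma cell and activated B-cell program fell, 16 of 18 with 1 higher (17 and 1 adjusted over the list alone) and a median of -0.77, which was -0.04 with spike-in scaling. The kinase PIM2 fell by 2.28 ± 0.07 on the log2 scale, its relative PIM1 by 1.70 ± 0.07 and the transcription factor BATF by 3.46 ± 0.13. NF-kB target genes were lower in 24 of 29 cases and higher in 2 (24 and 2 adjusted over the list alone), with a median of -1.30 and of -0.58 with spike-in scaling. The chemokine receptor CCR7 fell by 3.52 ± 0.07, from 458 ± 9.80 to 40.0 ± 2.60 CPM (SD, n = 2), whereas REL rose by 2.72 ± 0.11. Relative to other genes, 31 of 37 nuclear complex I genes were lower and 1 higher (31 and 1 adjusted over the list alone), with NDUFS6 at -1.13 ± 0.07. The list median was -0.73, and -0.01 with spike-in scaling. Likewise 74 of 75 cytosolic ribosomal protein genes were lower and 0 higher (74 and 0 adjusted over the list alone), with a median of -0.85, which was -0.13 with spike-in scaling, and many of these genes have pseudogene copies that share reads. Of 29 DNA damage repair genes 19 rose and 0 fell (20 and 0 adjusted over the list alone), such as FANCI (1.08 ± 0.06) and the checkpoint kinase ATR (1.20 ± 0.08). Camera called 27 lists with the preset correlation, and with estimated correlations the plasma cell list (adjusted p = 0.00587) and complex I (adjusted p = 0.0103), while the NF-kB, ribosomal protein and DNA repair lists each stood at adjusted p = 0.0577 with an estimated correlation. Log2 fold change also rose with the genomic span of genes in U-2932 (Spearman's rho = 0.34 across genes, against -0.01 to 0.09 in the other lines). Whether this trend moved the NF-kB, plasma cell or DNA repair lists was not tested.

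**Figure D2:**
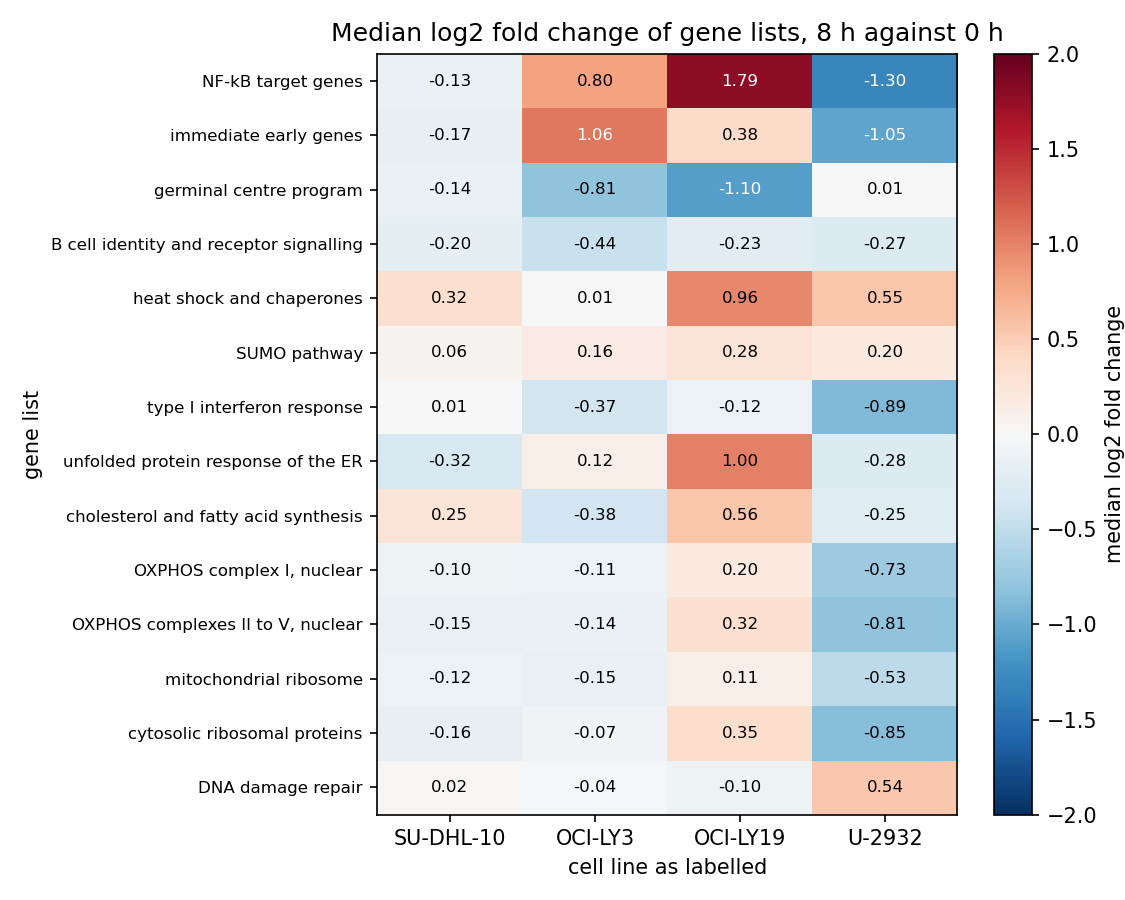
Median log2 fold change (colour scale, 8 h of TAK-981 against 0 h under TMM scaling) of 14 gene lists fixed beforehand (vertical axis) in each cell line as labelled (horizontal axis), from -1.30 for NF-kB target genes in U-2932 to 1.79 in OCI-LY19. The sign turns with spike-in scaling for the mitochondrial ribosome (0.20), B-cell (0.45), unfolded protein response (0.44) and cholesterol (0.48) lists in U-2932, for complex I (0.14 and 0.04), complexes II to V (0.11 and 0.01) and the mitochondrial ribosome (0.10 and 0.02) in OCI-LY3 and SU-DHL-10 and for cytosolic ribosomal proteins (0.19) and DNA repair (0.21) in OCI-LY3, without TMM scaling for complex I (-0.03) and the mitochondrial ribosome (-0.13) in OCI-LY19 and heat shock genes (-0.03) in OCI-LY3, and with RLE scaling for the germinal centre list (-0.01) in U-2932.

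The response differed between lines for 9268 of 17327 genes, or 53.5%, by the test of a difference in change (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 degrees of freedom between lines). NFKBIA, the inhibitor of NF-kB, moved by -0.86 ± 0.08 in SU-DHL-10, 0.81 ± 0.07 in OCI-LY3, 1.72 ± 0.07 in OCI-LY19 and -1.48 ± 0.08 in U-2932. HSPA5 fell in SU-DHL-10 (-0.92 ± 0.06) and U-2932 (-0.53 ± 0.06) and rose in OCI-LY19 (1.89 ± 0.06). BCL6 fell in OCI-LY3 (-2.32 ± 0.08) and OCI-LY19 (-1.55 ± 0.08) and rose in U-2932 (0.71 ± 0.08). MYC, the growth regulator, rose in SU-DHL-10 (0.37 ± 0.07) and fell in OCI-LY3 (-0.90 ± 0.07), OCI-LY19 (-1.01 ± 0.07) and U-2932 (-0.44 ± 0.07). Between OCI-LY3 and OCI-LY19, 1563 genes were higher in both and 1337 lower in both, where independent lists would share 489 and 383, and 201 went opposite ways where 869 would. Between OCI-LY19 and U-2932, 2485 genes went opposite ways, where independent lists would give 1728. In this pair 1131 genes were higher in both and 734 lower in both, where independent lists would share 974 and 761. Over all genes the log2 fold changes of these 2 lines were nearly uncorrelated (r = -0.04), and the direction of calls depends on the scaling. In all, 184 genes rose and 90 fell in every line, against 8.03 and 6.05 for independent lists. That reference is low, since OCI-LY3 and OCI-LY19 may be related or shared cells and genes with many counts are easier to call in every line. CPEB2 rose by 1.19 ± 0.23, 1.20 ± 0.14, 1.37 ± 0.11 and 1.21 ± 0.18, and TSC22D3 fell by 1.51 ± 0.31, 1.67 ± 0.17, 1.87 ± 0.14 and 2.92 ± 0.20 (SU-DHL-10, OCI-LY3, OCI-LY19 and U-2932). Without replicate 1 or replicate 2 of SU-DHL-10 at 8 h, 161 and 177 genes were called in every line.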

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

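The tests for material carried over between libraries and for the effect of scaling on NF-kB genes were chosen only after the results were seen, as were the joint correction for 2 trends, the reading of the trends in OCI-LY19, the need for the window ratio to hold at both times, and the genes used to compare 2 lines at 0 h.

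The response to 8 h of TAK-981 differed between the 4 lines for 9268 genes (edgeR's quasi-likelihood test of the difference, Benjamini-Hochberg adjusted). Against the mean of the other lines, the change differed for 3540 genes in SU-DHL-10, 2799 in OCI-LY3, 6163 in OCI-LY19 and 7366 in U-2932. The 10 genes with the smallest p among those at 5 CPM or more had adjusted p = 1.60e-36 (SLC12A7), 4.83e-32 (CCR7), 6.94e-28 (MKNK2, NECTIN1 and ICAM1), 1.17e-27 (HSPA5, CCL4 and NFKB2), 5.34e-27 (NFKBIA) and 1.46e-26 (RUBCNL) in the same edgeR test. MKNK2, a kinase of the translation factor eIF4E, changed by -0.39 in SU-DHL-10, 0.98 in OCI-LY3, 2.17 in OCI-LY19 and -0.77 in U-2932 on the log2 scale. CCL4, a chemokine, rose by 3.05 in OCI-LY3 and 3.63 in OCI-LY19 and fell by 2.63 in U-2932.

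Lists are given here where the difference from the mean of the other lines passed camera with both the preset and an estimated correlation, a choice made after the results were seen, as median log2 differences under TMM scaling. In OCI-LY3 these were NF-kB target genes (0.76), immediate early genes (0.96), the ATF4 and amino acid stress response (0.32), S phase and replication (-0.18) and cholesterol and fatty acid synthesis (-0.59). In OCI-LY19 they were NF-kB target genes (1.91), the unfolded protein response (0.98), cytosolic ribosomal proteins (0.72), class I antigen presentation (0.69), complexes II to V (0.69), complex I (0.54), cholesterol and fatty acid synthesis (0.53) and the proteasome (0.51). Within OCI-LY19, removal of a trend with expression level took the median log2 fold change of cytosolic ribosomal proteins from 0.35 to -0.04, of complexes II to V from 0.32 to 0.15 and of complex I from 0.20 to 0.11. In U-2932 they were NF-kB target genes (-2.11), the plasma cell and activated B-cell program (-0.88), complex I (-0.75) and DNA damage repair (0.51).

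The libraries labelled OCI-LY3 and OCI-LY19 resembled each other, with 18 genes at 10 CPM or more in 1 and under 0.1 of that in the other at 0 h, against 506 to 635 for the other pairs. The 18 lie within the range of a line at 8 h against itself at 0 h (0 in SU-DHL-10 to 19 in OCI-LY19). Material with the expression of the OCI-LY19 libraries, carried into those labelled OCI-LY3, is argued against. Of genes on in OCI-LY19, 13 lay under 0.1 of that level in OCI-LY3 at 0 h and 14 at 8 h (FBN2 11.36 and 0.08 CPM, USP2 12.22 and 0.14 CPM). OCI-LY19 cells in another state stay open, since OCI-LY19 at 8 h against itself at 0 h gave 19 genes over both directions. The reverse, with 5 such genes at 0 h and 3 at 8 h, stays open because the genes are few (PTPRR, at 6.17 CPM in OCI-LY3 and 0 in OCI-LY19, goes against it but is 1 gene). The spread of log2 ratios over windows of neighbouring genes, relative to shuffled order, was 2.28 at 0 h, below the other pairs (2.40 to 3.75), as written beforehand for 1 line under both labels, but 2.83 at 8 h, within the other pairs (2.23 to 3.52). Before division by the shuffled spread, the spread was 0.1213 at 0 h and 0.1219 at 8 h. Both lay below the other pairs (0.207 to 0.4278 at 0 h and 0.2001 to 0.3256 at 8 h). The shuffled spread fell from 0.0532 to 0.04303, so the ratio rose through its divisor. So 1 cell line under both labels and separate lines of similar origin cannot be told apart. The ratio gave different answers at the 2 times, and lines against themselves at 8 h and 0 h (1.28 to 2.76) overlapped with pairs of lines. The undivided spread of U-2932 against itself (0.219) overlapped with them too. The labels may therefore cover related or shared cells, and results that count OCI-LY3 and OCI-LY19 as separate lines rest on the labels.

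Genes of complex I, complexes II to V, the mitochondrial ribosome and cytosolic ribosomal proteins were lower in U-2932, with a median of -0.71 over the 4 lists under TMM scaling, where the spike-in medians were -0.01, -0.08, 0.20 and -0.13. A trend with gene span as the whole cause is argued against, since the median was -0.45 after its removal, and so is a trend with expression level (-0.73). After both were removed together the median was -0.37, so trends may account for part of the fall. How the spike-ins were dosed is not given, so a fall of these mRNAs and a rise of most others stay open. A biological cause was not tested.

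NF-kB target genes fell in U-2932 (median -1.30) and rose in OCI-LY3 (0.80) and OCI-LY19 (1.79), while SU-DHL-10 had a median of -0.13 (0.00 with spike-in scaling) and a camera call for lower (adjusted p = 0.00823) that was lost without its replicate 1 at 0 h (adjusted p = 0.351) and on its own estimate (adjusted p = 0.380 with an estimated correlation). Scaling is argued against as the cause, since with spike-in scaling the medians were -0.58 in U-2932 and 1.77 in OCI-LY19, and so is a single library, since the median in U-2932 was -1.24 or lower when any 1 of its 4 libraries was left out. The direction did not follow the spike-in share, which was low in OCI-LY3 and high in OCI-LY19 and U-2932. A difference between the lines in NF-kB activity under TAK-981 may explain it, a hypothesis drawn from these data that was not itself tested. A different course over 8 h in culture was not tested and stays open, as no vehicle sample was analysed here. Nor was the trend with gene span in U-2932 tested for this list.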

How the results depend on the processing

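Spike-in scaling and the subsets by spike-in share were chosen after seeing the data, and the other alternatives before the data were examined. Of the values recomputed for named genes, 15489 stayed on their side of the threshold, 599 lost the call, 184 gained it and 4 reversed. A turn of direction was counted as reversed only where the main or the alternative fit passed the threshold. Direction was therefore not judged for values called in neither fit, and the test of a difference between lines gives none. For lists, by the same rule, 1637 stayed on their side, 124 lost the call, 59 gained it and 4 reversed. Leaving out single libraries gave 10424 of the 15489 and 1158 of the 1637. Neither spike-in scaling nor the subsets by spike-in share enter these numbers, as named genes and single lists were not retested there. The list medians that turned sign with spike-in scaling are given in the Results.

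Leaving out 1 library gave 1060 to 2419 genes in SU-DHL-10 (the lowest without replicate 1 at 8 h), 161 to 295 genes called in every line (the lowest without the same library), and 1813 to 2196 genes that differed in OCI-LY3 from the other lines (main value 2799, the lowest without its replicate 2 at 8 h). The other ranges were 3244 to 4819 in OCI-LY3, 5278 to 7114 in OCI-LY19, 7341 to 9096 in U-2932 and 2414 to 3280 across lines. A lone library left in a group was assumed to vary like the other groups.

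A log2 fold change above 1 as a further threshold left 231, 974, 1831 and 2865 genes in SU-DHL-10, OCI-LY3, OCI-LY19 and U-2932 and 663 across lines, by its construction. Spike-in scaling gave 773 in SU-DHL-10 and 4206 in OCI-LY19. Across lines, a replicate block gave 1215 genes, leaving out OCI-LY3 1409, the mean of the 4 line contrasts 7112, the low-share lines 1911 and the high-share lines 1758. Leaving out SU-DHL-10, OCI-LY19 or U-2932 instead gave 3393, 2893 and 3385, so fewer samples alone do not account for the 1409. With an estimated correlation, camera called 0 lists across lines, 0 in SU-DHL-10, 1 in OCI-LY3, 1 in OCI-LY19 and 2 in U-2932. Fry, which does not set a list against other genes, called 11, 18, 18, 33 and 33 in the same order. Leaving out U-2932 reversed the direction across lines of cytosolic ribosomal proteins (camera adjusted p = 0.539), the plasma cell list (0.246), immediate early genes (0.0211) and DNA damage repair (0.946). The mean of the 4 contrasts reversed PRDM1 (0.11) and EBI3 (-0.14), and the lack of TMM reversed UBA2 (-0.075) and TFAM (-0.08) in OCI-LY19. Apart from the fold threshold, the cause was not tested.

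The replicate block gave 2004, 4274, 6616 and 8609 genes in the 4 lines. The numbers do not pair the samples, as deviations from the group mean at 0 h and 8 h correlated across genes with r = 0.016, 0.034, -0.012 and -0.012. DESeq2 called 2145, 4024, 6120 and 7999 in the lines and 3835 across. Depth limits genes with few counts: HMOX1 had 7 counts in OCI-LY3 at 0 h and 0 at 8 h, at least 2.80-fold lower.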

Other observations

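The search for other splits of the samples was chosen before its result was seen, and the genes below were taken by the rule for named genes.

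Several metabolic and cell cycle genes changed in the test across the 4 lines, which does not test whether the lines were alike (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8 against 8 libraries). TXNIP, which restrains glucose uptake, fell by 0.80 ± 0.11 on the log2 scale, and the glucose transporter SLC2A3 rose by 0.90 ± 0.16. In the tests within a line, HMOX1, which breaks down heme, fell by 3.36 ± 0.57 in OCI-LY19 and by 3.26 ± 0.28 in U-2932 on the same scale. Across lines, camera called neither the glycolysis list, which holds SLC2A3, nor the oxidative stress list, which holds HMOX1. The replication helicase genes MCM5 (-0.66 ± 0.09) and MCM6 (-0.30 ± 0.05) and the DNA glycosylase UNG (-0.49 ± 0.10) fell, while cyclin E2 (CCNE2) rose by 0.60 ± 0.11. These are members of the S phase and replication list, which camera did not call (adjusted p = 0.458), with 5 of 30 lower, 1 higher and 24 not called (6 lower and 2 higher adjusted over the list alone) and a median of -0.04, which was 0.23 with spike-in scaling. In the list of G2 and M phase 9 of 30 members rose and 1 fell (14 and 1 adjusted over the list alone), such as the centromere histone CENPA (0.89 ± 0.11), cyclin B1 (CCNB1, 0.47 ± 0.09) and CDK1 (0.41 ± 0.08), with camera adjusted p = 7.50e-05, and adjusted p = 0.681 with an estimated correlation. Its median across lines was 0.23, and by line it was -0.08 in SU-DHL-10 (0.05 with spike-in scaling), 0.24 in OCI-LY3, 0.16 in OCI-LY19 (-0.08 without TMM scaling) and 0.59 in U-2932.

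Of 25 p53 target genes 6 fell and 0 rose (8 and 2 adjusted over the list alone), such as the antiproliferative gene BTG2 (-0.93 ± 0.11), GADD45A (-0.55 ± 0.08) and the nuclease AEN (-0.51 ± 0.10). The list median was -0.24, and 0.04 with spike-in scaling. Its camera call (adjusted p = 0.00777) was lost without the U-2932 line (adjusted p = 0.246), and likewise on its own estimate (adjusted p = 0.467 with an estimated correlation). LCK, a SRC-family kinase best known from T cells, fell by 0.81 ± 0.08, and did so in each line (-0.68, -0.90, -0.96 and -0.75).

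Other splits of the 16 libraries into 2 and 2 within each line were tried. Of 100 splits, the real one included, only the real one called as many as 3128 genes (edgeR). The highest other split called 2168 and either kept or fully swapped the times in 3 of the 4 lines. Chance assignment of these libraries to times is argued against for the count across lines, at 1 in 100, the lowest level that 100 splits can give. As replicates may be technical, this does not speak to separate cultures or to TAK-981 as the cause.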
